A study of Homo sapiens with 21 samples.

How the data were processed

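Proteins carrying a FLAG-HA tag were crosslinked to RNA in human Flp-In T-REx 293 cells, an established kidney-derived line, after labelling of new RNA with 4-thiouridine. In PAR-CLIP a crosslinked 4-thiouridine is read as C in place of T, which marks the bound site. In the fluorescent protocol (fPAR-CLIP) the RNA was tagged with a fluorescent adapter, and in the older protocol with a radioactive label. The series listed 21 samples, of which 17 had cluster files: 6 libraries of AGO2, the protein that carries microRNAs, 4 of FUBP3, 4 of KHSRP, 2 of U2AF1 and 1 of CPSF1. The 4 AGO2 samples without a cluster file, 3 of them labelled as crosslinked at 254 nm, were not analysed here. Raw reads were not used here.

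Each deposited file listed clusters called in a single library, with read counts, counts of distinct read sequences and counts of T-to-C events per cluster. The deposited values were raw counts, and the deposited conversion values were a fraction of the reads of each cluster. Per the labels, the authors used bcl2fastq 2.20.0, cutadapt 1.15 and the human build hg38. The aligner, the cluster caller and the annotation were not given in the sources used here. The smallest cluster held 5 reads, except in the U2AF1 files, where it held 4. Reads outside clusters were not in the files, so the total of reads in clusters was used in place of library depth. That total ranged from 75383 reads (U2AF1, 15 U/ml) to 2172248 reads (KHSRP, 0.15 U/ul).

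Builds were checked by asking whether overlapping clusters of different libraries had the same base at the same position. The hg38 libraries had the same base at 100% of positions compared. The 4 AGO2 libraries made with or without a urea gel had the same base at 100% of positions among themselves, but at 29.4% to 31.4% against hg38 libraries, so their coordinates belonged to another build. They were set against the other libraries by position only in checks of builds and gene names, and no coordinate from them is given. AGO2 clusters of the different builds were compared by shared stretches of at least 18 nt of sequence. The RNase T1 libraries of FUBP3 and KHSRP had hg38 coordinates, but 61.4% and 62.0% of their clusters had no annotation. The deposited gene matched the gene at that RefSeq position for 41.1% and 44.8% of their named clusters, against 98.8% and 99.1% in the fluorescent libraries at 0.5 U/ul. For these libraries the genes were therefore assigned from RefSeq gene spans, a choice made after the data were seen, and their deposited region classes were not used here. Gene strands were learned from 631109 clusters for 11985 genes, with a majority of 90% required. A gene was named for 70.0% to 93.9% of the clusters in the other libraries, and clusters without a gene name stayed out of gene sums. Coordinates are given in hg38, counted from 1.

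Reads were summed per gene within a library and set over all reads in its clusters. Clusters counted as shared when they overlapped by at least 1 nt on the same strand (bedtools 2.31.1). Shares of clusters carry Wilson intervals at 95%. Intervals cover counting error only, since reads and clusters are not independent molecules. Motif shares were compared with 10 shuffles of each cluster sequence that kept its dinucleotides, and hexamers were ranked among those in at least 1% of clusters. For AGO2 the motifs were matches to microRNA seeds, positions 2 to 8, of 14 families chosen as expressed in these cells and 4 families chosen as background. Distances to gene 3' ends were set against the same clusters moved by 5000 nt. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

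The AGO2 gel comparison was the only one with replicates, 2 libraries per group. Genes with at least 10 reads over the 4 libraries and a cluster in each were tested with edgeR quasi-likelihood, with DESeq2 as the other tool, and adjusted p-values under 0.05 were called. Single values per library were compared with two-sided exact permutation tests, which at 2 against 2 cannot go below 0.3333. Lists with at least 5 tested genes were tested with camera, at its preset and with an estimated correlation. The p-values measure spread between libraries, which may be technical. For FUBP3 against KHSRP, genes with at least 50 reads in each of the 6 fluorescent libraries were compared at each RNase I dose, and a gene counted only when the direction was the same at all doses. List medians were ranked against 10000 random lists of equally abundant genes. All other comparisons had 1 library per group and no test.

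The 10 gene lists were microRNA target mRNAs, mRNAs with AU-rich elements, replication-dependent histones, SR and hnRNP proteins, cytoplasmic ribosomal proteins, mitochondrially encoded RNAs, long noncoding RNAs, 3' end processing factors, the FUBP family with the tagged proteins, and short noncoding RNA genes, a list taken by name pattern that also holds microRNA host genes such as MIR17HG and MIR99AHG. Lists were matched by exact gene name. NORAD, named LINC00657 in the fluorescent FUBP3 and KHSRP libraries, therefore stayed out of the long noncoding list there. Named genes followed a rule. In the gel comparison they were up to 10 called genes each way whose groups did not overlap, with the largest fold. For FUBP3 against KHSRP they were the 10 genes each way with the largest of the smallest ratios over the doses, not all of which are reported. For a pair of single libraries they were the 5 genes each way with the largest ratio, and in each library the 5 genes with the most reads. List members and the mRNAs of the tagged proteins could always be named. Samples, comparisons, lists, the naming rule and most alternatives were fixed before the data were examined. Alternatives covered read minimums of 10, the top 1000 clusters, overlap of 50% of each cluster, read shares, other scalings, left-out libraries, pairing by replicate letter and other backgrounds for motifs. Added after the data were seen were a minimum share of reads matched over libraries, clusters with at least 3 distinct sequences, distinct sequences in place of reads, and the gel comparison without short noncoding RNA genes.

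The procedures were tested on simulated data. With 100 changed genes per fold, the gel test recovered 18% of 2-fold and 71% of 4-fold changes and made 2 false calls. The comparison over doses recovered 100% of planted differences, and 26.7% of unchanged genes had the same direction at every dose, near the 25% that chance gives. Its simulated counts had counting error alone, without further spread between libraries or a shift between proteins. Recovery was therefore near certain, and neither value carries over to the real libraries. The motif search found 600 of 600 planted sites, which was bound to happen and tests the search alone, not the ratios. A background seed match that was not planted gave 1.31 times the shuffled level in the 20000 random sequences. The ratio of a rare motif can thus lie this far from 1 without enrichment.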

Results

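The series tested a PAR-CLIP protocol without radioactivity on 5 RNA-binding proteins in Flp-In T-REx 293 cells. Fluorescent libraries were made for AGO2 at 0.15 and 1.5 U/ul RNase I, CPSF1 at 0.5 U/ul, FUBP3 and KHSRP at 0.15, 0.5 and 1.5 U/ul, and U2AF1 at 1.5 and 15 U/ml RNase A+T1. Radiolabelled libraries were made for FUBP3 and KHSRP with RNase T1 at 0.5 U/ul, and for AGO2 with RNase T1 at 1 U/ul, 2 with a urea gel step and 2 without it. Clusters per library numbered from 2305 (AGO2 with the gel, B) to 180358 (FUBP3 at 0.5 U/ul). Outside the AGO2 gel libraries each condition had 1 library, so no spread between replicates was available there.

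The libraries of the 5 proteins differed in the regions and RNAs they covered. U2AF1 cells were labelled with 250 uM 4-thiouridine for 2 h and the others with 100 uM for 8 to 12 h, and the RNase differed too, so for U2AF1 these differ together with the protein. At 0.15 U/ul, 38.7% of AGO2 clusters lay in 3' UTRs (95% Wilson interval 36.8 to 40.7) and 10.5% in introns. CPSF1, the cleavage and polyadenylation subunit, had 67.9% of clusters in introns and 10.0% in 3' UTRs. FUBP3 and KHSRP, related KH-domain proteins, had intron shares of 64.0% and 78.1% at 0.5 U/ul, and 3' UTR shares of 18.9% and 9.23%. By reads the order of the proteins turned, with 3' UTRs at 37.0% in FUBP3, 12.6% in KHSRP, 10.9% in CPSF1 and 3.97% in AGO2. U2AF1, which binds the AG at the end of introns, had 5.80% of clusters (5.31 to 6.33) and 11.5% of reads at 3' splice sites at 1.5 U/ml. RNAs with the most reads differed too. AGO2 reads were led by RP4-561L24.3, the vault RNAs VTRNA1-2 (6.58% of reads) and VTRNA1-3 (6.45%), whose similar sequences leave the split between them uncertain, and the microRNA genes MIR320A (4.56%) and MIR93 (4.46%). CPSF1 reads were led by the spliceosomal RNU5D-1 (0.405%), followed by ERC1, XIST, CTC1 and SLIT2. In U2AF1, 5.8S rRNA names led, with 2.78% for the merged name RNA5-8S5|hsa-mir-3687-1, while the small nucleolar SNORA75 held 1.95%. These rRNA names are near-identical copies, so their reads cannot be placed on a single locus. 

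**Figure D1:**
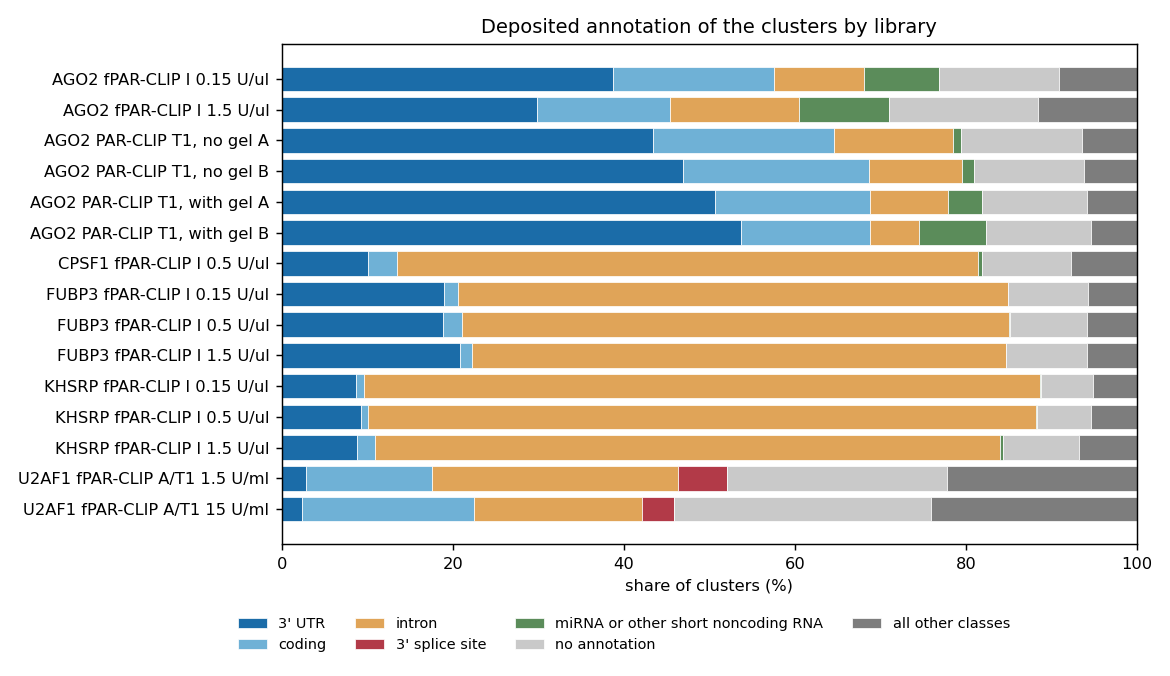
Share of clusters (%) in each annotated region, by library, for libraries whose region classes could be used. In FUBP3 and KHSRP at 0.5 U/ul introns held 64.0% and 78.1% of clusters, and AGO2 at 0.15 U/ul had 38.7% in 3' UTRs.

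AGO2 at 0.15 and 1.5 U/ul RNase I addressed how RNase dose changes the recovered sites. The share of 3' UTR clusters was 38.7% at 0.15 U/ul and 29.8% (28.0 to 31.7) at 1.5 U/ul, while introns held 10.5% and 15.1%, and microRNAs held 33.0% and 44.5% of reads. At 1.5 U/ul the most read genes were MIR320A (8.03%), MIR93 (6.70%), MIR20A (5.77%), RP4-561L24.3 (5.10%) and MIR17 (4.67%). Of 180 genes with at least 50 reads in both libraries, the small nucleolar SNORA19 (2.97-fold), MIR26B (2.51-fold), MIR34A (2.44-fold), KLHL15 (2.42-fold) and OIP5-AS1 (2.34-fold) were furthest above at 0.15 U/ul. The linker histone HIST1H1E lay furthest toward 1.5 U/ul, at a log2 ratio of -3.11, followed by LINC00324, RNA5SP387, AC018766.4 and MIRLET7F1. Of the clusters at 0.15 U/ul, 39.2% (37.3 to 41.2) overlapped a cluster at 1.5 U/ul, and these held 91.7% of reads. Across 785 genes the Spearman correlation was 0.779, genes not being independent replicates. 

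Fluorescent and radiolabelled AGO2 libraries were set side by side by sequence. At 0.15 U/ul, 39.6% (37.7 to 41.5) of fluorescent AGO2 clusters shared a stretch of at least 18 nt with the radiolabelled library A without the gel, and those clusters held 90.7% of reads. The shares were 36.8% for library B without the gel and 24.7% and 17.3% for the libraries with it, which had fewer clusters. With KHSRP at 1.5 U/ul, a protein with other targets, the share was 9.20%, and those clusters held 51.6% of reads. MIR320A and MIR93 were among the 5 most read genes in every AGO2 library with a file. Replication-dependent histone mRNAs held 4.78% and 4.80% of fluorescent AGO2 reads and between 0.419% and 0.505% in the radiolabelled ones. Gene totals correlated at Spearman 0.329 and 0.275 at 0.15 and 1.5 U/ul with library A without the gel, 0.399 and 0.310 with B, and 0.425 to 0.465 with the libraries with the gel, across genes that are not independent replicates. RNase, label and build all differed between these libraries. 

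Seed matches of expressed microRNAs marked the AGO2 clusters. Matches to the 14 expressed families stood in 20.6% of AGO2 clusters at 0.15 U/ul, 5.37 times the shuffled level, and in 15.3% at 1.5 U/ul, 4.68 times. In the radiolabelled AGO2 libraries the ratios were 4.28 and 4.89 without the gel and 6.23 and 7.45 with it. In CPSF1, FUBP3, KHSRP and U2AF1 libraries they lay between 0.99 and 1.17. The 4 background families gave ratios between 0.54 and 1.10 in AGO2. 

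**Figure D2:**
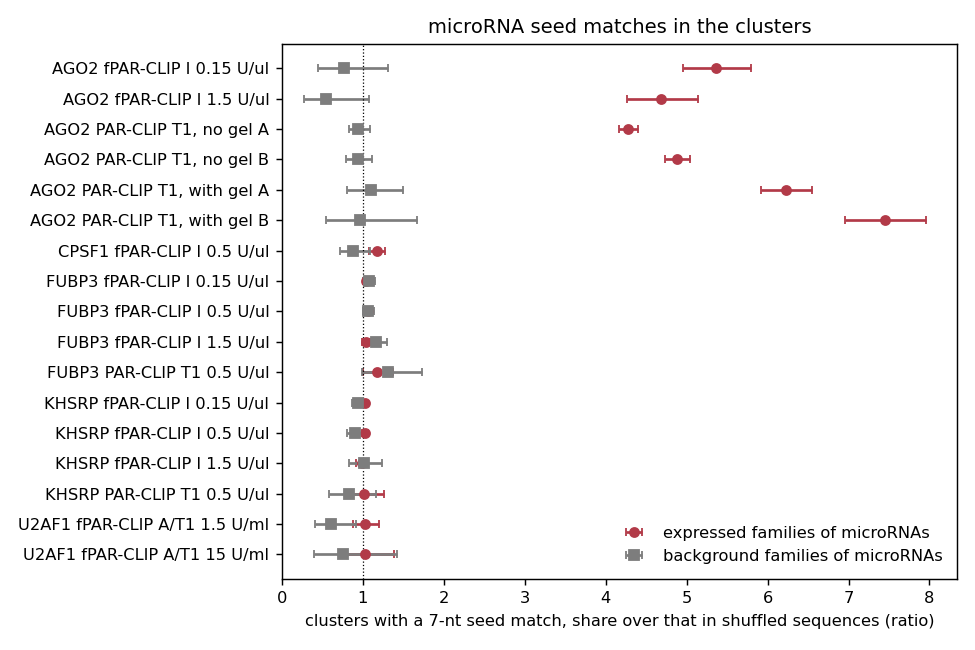
Ratio of clusters with a seed match to the same in dinucleotide shuffles, for expressed and background microRNA families in each library, with error bars from 95% Wilson intervals. AGO2 libraries ranged from 4.28 to 7.45 for expressed families.

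The urea gel step for size selection was compared in replicate AGO2 libraries. With the gel, microRNAs held 52.3% and 59.7% of reads, and without it 34.9% and 40.4%. MIR17HG, host of the miR-17-92 microRNAs, and MIR320A were the genes higher with the gel, and EXOC8, an exocyst subunit in vesicle tethering, was higher without it. In edgeR, EXOC8 had a log2 ratio without over with the gel of 3.36 ± 0.41 (SE, adjusted p = 0.0170), MIR320A -1.22 ± 0.13 (adjusted p = 0.0168) and MIR17HG -0.70 ± 0.08 (adjusted p = 0.0170), each with no overlap between the groups of 2 libraries. These were the 3 calls among 1121 genes, of which 529 had no overlap, 33.3% being the chance share, and 149 had an unadjusted p under 0.05. EXOC8 counted 533 and 520 reads without the gel and 13 and 5 with it, and its largest 3' UTR cluster held 346 and 391 of the former from 3 and 6 distinct sequences.

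Of the short noncoding RNA genes tested, 6 lay above 0 and 101 below it; 2 were called, both higher with the gel, and 11 passed when adjusted over the list alone. Their median log2 ratio was -0.53 (camera adjusted p = 1.90e-11, adjusted p = 0.375 with an estimated correlation), with MIR10A at -0.59, MIR93 at -0.34 and MIR484 at -0.04. With a minimum share of reads matched over the libraries, chosen after seeing the data, the call ended, at a median of -0.08 over 99 genes, 61 of them lower without the gel (adjusted p = 0.147, adjusted p = 0.482 with an estimated correlation). The 13 SR and hnRNP genes had a median of 0.54 (adjusted p = 0.0945, adjusted p = 0.592 with an estimated correlation) and the 12 ribosomal protein genes -0.44 (adjusted p = 0.0945, adjusted p = 0.515 with an estimated correlation). Medians were 0.02 for 14 microRNA targets (adjusted p = 0.569), 0.15 for 6 mRNAs with AU-rich elements (adjusted p = 0.376) and -0.12 for 9 histones (adjusted p = 0.569), and none of these had a call. Too few members were tested for a list test in the long noncoding RNAs (4 genes, 1 call, MIR17HG, which also passed when adjusted over the list alone), the 3' end factors (3 genes, median -0.48) and the FUBP family with tagged proteins (2 genes, median 1.37, 1 passing when adjusted over the list alone). No mitochondrially encoded RNA was tested. 

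Libraries without the gel held 39070 and 22573 clusters, against 6753 and 2305 with it, a 7.53-fold difference of geometric means (exact permutation p = 0.3333, two-sided, the smallest this design gives). They covered 963969 and 577727 nt at a mean of 23.8 and 26.9 reads per cluster, against 172685 and 60121 nt at 27.1 and 33.7. Clusters in 3' UTRs made up 45.1% ± 2.54 (SD, n = 2) without the gel and 52.2% ± 2.19 with it, a difference that turned to 2.70 points higher without the gel over clusters with at least 10 reads. The median cluster length was 22 nt in both libraries without the gel and 23 nt in both with it. With the matched minimum both length and cluster number turned. Lengths were then 31 and 30 nt without the gel and 25 and 23 nt with it, and cluster numbers 1214 and 1341 against 1569 and 2305. Seed matches stood in 12.8% ± 2.43 and 22.6% ± 6.07 of clusters, and T-to-C shares were 11.3% and 11.1% without and 11.6% and 11.2% with the gel. With the matched minimum the microRNA read shares were 60.9% and 60.1% without and 63.8% and 59.7% with the gel, the seed share turned higher without the gel by 9.13 points, and edgeR made 0 calls among 494 genes (40 at an unadjusted p under 0.05; smallest adjusted p 0.331), with MIR320A at a log2 ratio of -0.78 and MIR17HG at -0.26, while EXOC8 was not among the genes tested. DESeq2 on the 1121 genes made 2 calls (97 at an unadjusted p under 0.05), with EXOC8 at an adjusted p of 2.87e-06, MIR320A at 0.0811 (log2 ratio -1.22) and MIR17HG at 0.510 (log2 ratio -0.70). By distinct sequences in place of reads EXOC8 had a log2 ratio of 2.14 and an edgeR adjusted p of 0.0728. Leaving out library A or B without the gel gave 13 and 14 calls and leaving out A with the gel 8, without MIR320A (log2 ratio -1.04, adjusted p = 0.145) and MIR17HG (log2 ratio -0.59, adjusted p = 0.381). Leaving out B with the gel gave 0 calls among 2847 genes (edgeR, 288 at an unadjusted p under 0.05; DESeq2 not run there), with log2 ratios of 3.34 for EXOC8, -1.21 for MIR320A and -0.61 for MIR17HG.

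**Figure D3:**
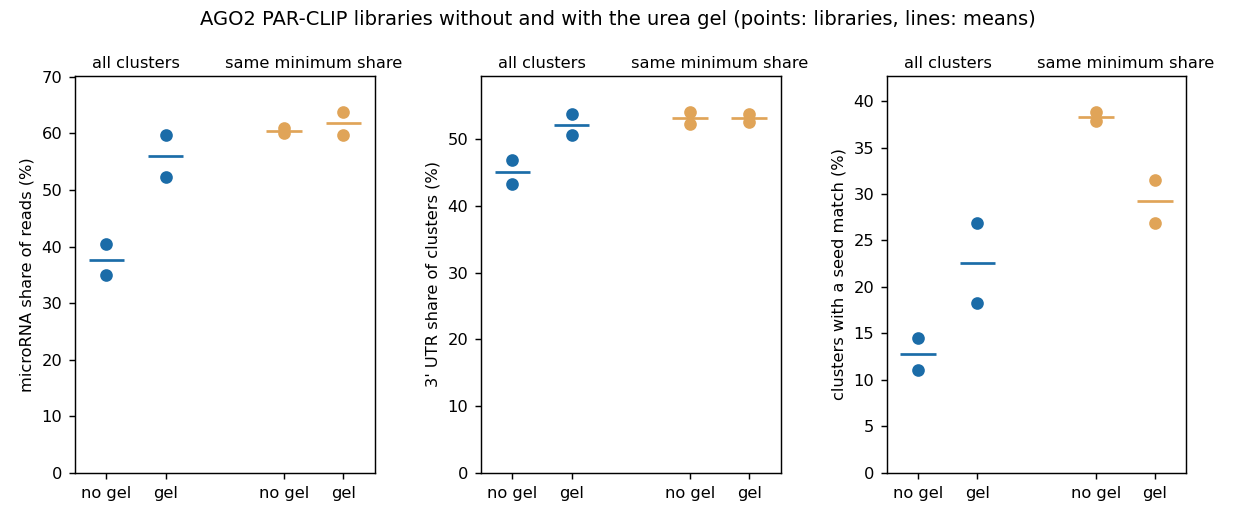
MicroRNA share of reads, 3' UTR share of clusters and share of clusters with a seed match (all %) in the 4 radiolabelled AGO2 libraries, with all clusters and with the same minimum share of reads; points are libraries and lines means. The microRNA shares were 34.9% and 40.4% without and 52.3% and 59.7% with the gel over all clusters, and 60.9% and 60.1% against 63.8% and 59.7% with the same minimum.

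FUBP3 and KHSRP were each profiled at 3 RNase I doses. ERC1 and XIST, the X-inactivation RNA, led FUBP3 reads at every dose, with 27334 ERC1 reads at 0.15 U/ul (1.62%), of which an intron cluster on chromosome 12 (hg38, 1200844 to 1202015) held 14571. XIST led KHSRP reads at 0.15 U/ul (1.88%) and 1.5 U/ul (1.75%), followed by ERC1 and HNRNPH1, a splicing regulator (0.586% and 0.878%). FUBP3 3' UTR shares were 19.0%, 18.9% and 20.8% of clusters from the lowest to the highest dose, and KHSRP shares 8.65%, 9.23% and 8.77%. By reads the FUBP3 shares were 37.2%, 37.0% and 30.5%, lower at the highest dose, and the KHSRP shares 11.8%, 12.6% and 10.3%. In FUBP3, HNRNPA2B1 (8.31-fold), NARS, HMGN4, MALAT1 and ZMAT2 were furthest toward 0.15 U/ul against 0.5 U/ul, and RBX1 (6.54-fold), POLE3, PRDX1, HSP90B1 and LSM4 furthest toward 0.5 U/ul. The HNRNPA2B1 ratio rested on a 3' UTR cluster of 2844 reads at 0.15 U/ul that had no counterpart at 0.5 U/ul. Between FUBP3 at 0.15 and 1.5 U/ul, NONO (4.95-fold), ATP6AP2, EWSR1, UGCG and ZNF850 were furthest toward the lower dose and MT-ND6 (14.4-fold), PARP1, NUP35, HEATR1 and TAF1A toward the higher. In KHSRP, MCM3AP, GINS1, MICU3, RNPS1 and ZNF37A were furthest toward 0.15 U/ul against 0.5 U/ul, and CTC-432M15.3 (28.4-fold), MALAT1 (23.5-fold), RBM27, RNU5D-1 and MIR16-2 furthest toward 0.5 U/ul. Between KHSRP at 0.15 and 1.5 U/ul, LUC7L2 (3.56-fold), RP6-24A23.7, EWSR1, ZNF721 and DNAH14 were furthest toward the lower dose and MALAT1 (66.4-fold), RNU5D-1, CTC-432M15.3, RNU11 and MIR16-2 toward the higher. Of FUBP3 clusters at 0.5 U/ul, 11.3% overlapped a cluster at 0.15 U/ul, and of those at 1.5 U/ul 13.9%. The KHSRP shares were 27.1% and 19.5%. Among clusters with at least 3 distinct sequences the FUBP3 shares were 34.1% and 50.0% and the KHSRP shares 44.6% and 54.5%, and with the top 1000 clusters FUBP3 at 0.5 U/ul reached 62.9%. Requiring overlap of 50% of each cluster lowered the shares of both proteins at both doses instead. Gene totals correlated at Spearman 0.911 to 0.854 between FUBP3 doses and 0.890 to 0.725 between KHSRP doses, across genes that are not independent replicates.

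**Figure D4:**
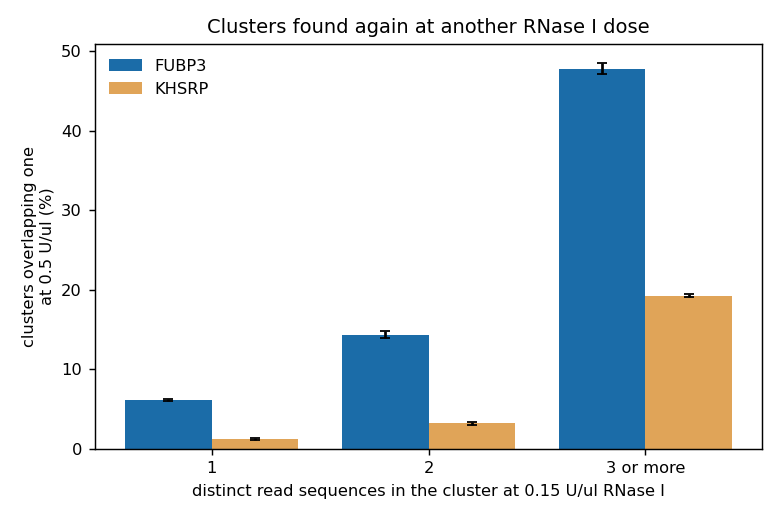
Share of clusters (%) of each protein at 0.15 U/ul that overlapped a cluster at 0.5 U/ul, by the number of distinct read sequences, with 95% Wilson intervals as error bars. FUBP3 shares were 6.11%, 14.4% and 47.8% for 1, 2 and 3 or more sequences.

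FUBP3 and KHSRP were compared dose by dose. FUBP3 had more reads than KHSRP on LINC00657 (NORAD), at least 3.76-fold at every dose, and on KLHL15 (2.53), the splicing factor SRSF2 (2.23), TMPO (2.13), SCML1 (2.00), IGF1R (1.98), HMGB2 (1.88), NLGN1 (1.87) and NUFIP2 (1.86). KHSRP had more reads on the cyclin-like CCNL2, where the smallest log2 ratio of FUBP3 over KHSRP was -3.02, on the splicing regulator HNRNPH1 (-2.85), and on TAF1D, CCNL1, TCAF1, RBM39, CCAR1, DDX46, TPR and IARS. KLHL15 had 96.0% of FUBP3 reads and 70.0% of KHSRP reads in its 3' UTR, and TMPO 87.3% and 42.1%. HNRNPH1 had 25.6% of FUBP3 reads and 2.10% of KHSRP reads there. Others went the opposite way, HMGB2 with 58.5% and 95.4%, CCNL2 with 26.9% and 32.2%, and TAF1D with 0% and 7.70%. 

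Of 789 genes, 13.6% were higher in FUBP3 and 60.1% in KHSRP at each of the 3 doses. The same sign was kept by 73.6%, against 25% by chance if neither protein is favoured. The median log2 ratio was -0.62, so 25% is not the chance level for this set. With median-of-ratios scaling the shares were 34.0% and 33.6%. With at least 10 reads in each library it was 967 against 1056 of 3563 genes, at a median of -0.02. Requiring at least 200 reads gave 2 against 52 of 61 genes, at a median of -1.17. The read minimum was a larger share of the KHSRP library at 1.5 U/ul (200210 reads) than of the FUBP3 one (810326). The split toward KHSRP moved with this minimum, so it cannot show which protein covers more genes. The 7 microRNA targets had a median of 0.48 and ranked above 99.3% of random lists, with 2 higher in FUBP3 and 2 in KHSRP. Their medians by dose were 0.66, 0.79 and -0.0034, which were not ranked separately. The 15 SR and hnRNP genes had a median of -1.13, above 6.34% of random lists, with 12 higher in KHSRP and SRSF2 in FUBP3. With median-of-ratios scaling the list medians were 1.11 for the microRNA targets and -0.50 for the SR and hnRNP genes. The other lists had too few members for ranking, among them HNRNPD with AU-rich elements at a mean log2 ratio of -1.32, RPL5 at -2.24, RPS24 at -2.56, CPSF6 at -1.44, PAPOLA at -1.04 and FUBP1 at -2.72. Among long noncoding RNAs FTX stood at -0.75, JPX at -1.50 and NEAT1 at -2.05, while MALAT1 was 4.95, -1.69 and -0.53 at the 3 doses. LINC00657, listed as NORAD and so missed by name, stood at 2.12 toward FUBP3. With it the long noncoding list would have had enough genes for ranking. From the short noncoding list the host gene MIR99AHG alone was measured (-0.26), which says nothing of a short RNA, and no histone or mitochondrially encoded RNA was. FUBP3 and KHSRP gene totals correlated at Spearman 0.787, 0.768 and 0.631 across genes at the 3 doses. 

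**Figure D5:**
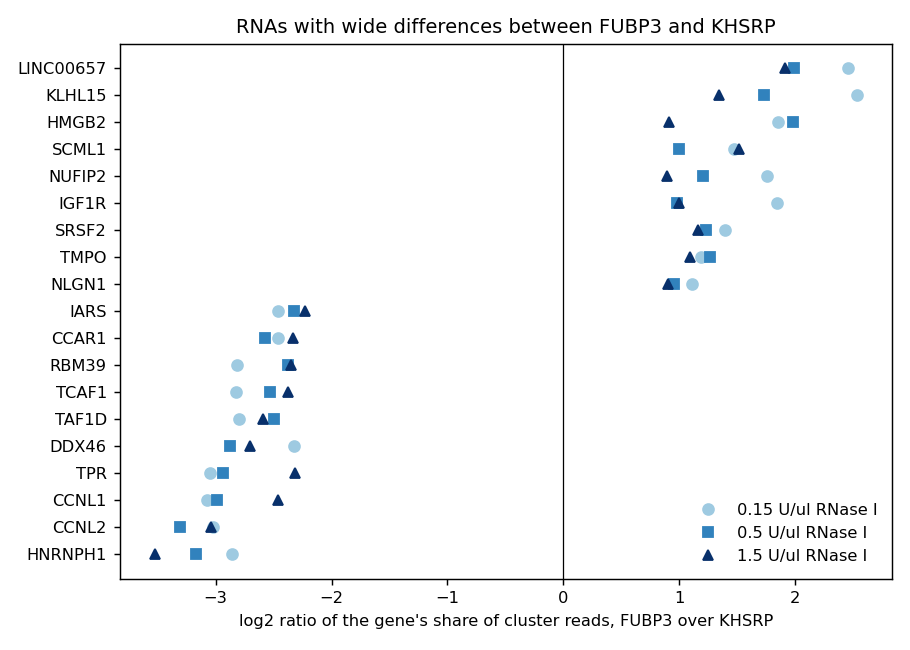
Log2 ratio of FUBP3 over KHSRP read shares for the named genes, a point per RNase I dose. LINC00657 and KLHL15 lay above 0 at each dose, and CCNL2 and HNRNPH1 below 0.

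Fluorescent RNase I and radiolabelled RNase T1 libraries of FUBP3 and KHSRP were compared at 0.5 U/ul, which addressed what the fluorescent protocol recovers. XIST and ERC1 were the RNAs with the most reads in FUBP3 and KHSRP libraries of both kinds, XIST with 5.51% of FUBP3 T1 reads and 0.941% of fluorescent reads, ERC1 with 4.25% and 1.43%. HNRNPH1 held 0.832% of KHSRP T1 reads and 0.808% of fluorescent reads. The insulin-signalling adaptor IRS4 (5.22-fold), PRKG1, ERBB4, IRF2BP2 and AUTS2 were furthest toward the fluorescent FUBP3 library, and HNRNPA2B1 (log2 ratio -4.42), RPL17, TSR1, RNPS1 and RP2 toward T1. HNRNPA2B1 held 0.509% of T1 reads and 0.0238% of fluorescent reads at 0.5 U/ul, where its strong 3' UTR cluster was missing, but 0.198% at 0.15 U/ul. For KHSRP, SERBP1 (3.03-fold), DDX17, DYNC2H1, HNRNPC and BRWD1 lay toward the fluorescent library, and HDAC8, SAAL1, CANX, RYR2 and MALAT1 toward T1. Of the T1 clusters, 37.2% (36.42 to 37.99) in FUBP3 and 22.7% (22.0 to 23.4) in KHSRP overlapped a fluorescent cluster, and 73.6% (72.4 to 74.8) of these lay in 3' UTRs by the annotation of the fluorescent cluster for FUBP3 and 19.7% (18.4 to 21.2) for KHSRP. By RefSeq span 99.0% and 97.4% of T1 genes were found in the fluorescent library, and gene totals correlated at Spearman 0.585 and 0.699 across genes. The fluorescent libraries held 9916 and 7679 genes by span, so high shares were likely for any protein. By deposited names, many of them mismatched, 71.1% of KHSRP T1 genes were in the FUBP3 fluorescent library and 64.5% in the KHSRP one. The FUBP3 and KHSRP T1 libraries also shared 86 clusters of the same position and read count. ERC1 and XIST were also among the most read genes of CPSF1. Enzyme, label and cluster number (14563 T1 against 180358 fluorescent for FUBP3) changed together, and with at least 10 reads the overlaps were 55.0% and 38.7%.

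A minority of CPSF1 clusters held a polyadenylation signal, and fewer lay at gene 3' ends, both above their backgrounds. AATAAA stood in 14.7% of CPSF1 clusters, 4.60 times the shuffled level, and ATTAAA in 5.91%, 2.23 times. AAATAA, a comparison hexamer with the bases of AATAAA in another order, stood in 7.62%, 2.37 times. The ATTAAA ratio was no higher than that of AAATAA, which can overlap AATAAA within the sequence AAATAAA. TTAAAA, with the bases of ATTAAA in another order, was not among the 10 highest hexamers in at least 1% of clusters. The lowest of those 10 stood at 2.22 times. Either hexamer stood in 19.6% (19.1 to 20.1) of all CPSF1 clusters, 82.4% of which rested on 1 distinct sequence, and in 33.1% of those with at least 3. It stood in 34.8% (32.8 to 36.8) of 3' UTR clusters, 19.3% of intron clusters and 4.55% of coding clusters. Within 100 nt of a gene 3' end lay 2.81% (2.59 to 3.04) of CPSF1 clusters, 14.6 times the level of clusters moved by 5000 nt, and 55.0% of them held either hexamer. The 3' end shares were 1.75% for FUBP3 and 0.955% for KHSRP, where 19.7% and 14.5% held one. With at least 3 distinct sequences 10.1% of CPSF1 clusters lay near an end. The mRNA of CPSF1 itself had 11 clusters, all coding, and reads from a tagged copy cannot be told from those of the native gene.

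U2AF1 at 1.5 and 15 U/ml RNase A+T1 was compared for the effect of dose. The 3' splice site held 5.80% (5.31 to 6.33) of clusters at 1.5 U/ml and 3.70% (3.05 to 4.47) at 15 U/ml, and introns held 28.7% and 19.7%. By reads introns held 23.6% and 32.4%, of which names from rRNA loci made up 35.8% and 71.9%, and without these names 16.9% and 12.2%. The 3' splice sites held 11.5% of reads at 1.5 U/ml and 6.20% at 15 U/ml. The 5' splice sites held 3.39% and 2.17% of reads, and 0.95% and 1.38% of clusters. The motif YTNCAG, an intron end, stood in 15.97% and 10.2% of clusters, 1.93 and 1.85 times the shuffled level, while YTNCAC gave 0.97 and 0.80 times. SMG1, a kinase of nonsense-mediated decay (3.33-fold), BRD2, ZNF711, MCM7 and HNRNPA1|RP11-968A15.8 were furthest toward 1.5 U/ml among 86 genes. CH507-528H12.1|RNA5-8S5, CH507-513H4.1, RNU1-148P, RNA5-8S5 and HNRNPL were furthest toward 15 U/ml, all but HNRNPL names from rRNA loci or small RNA copies, whose reads cannot be placed on a single locus. Of clusters at 15 U/ml, 17.7% (16.3 to 19.2) overlapped one at 1.5 U/ml, and with at least 10 reads the 3' splice-site shares were 12.8% and 7.24%. 

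Short motifs were counted in the clusters of the KH-domain proteins. TGTAT stood in 11.7% of FUBP3 and 15.98% of KHSRP clusters at 0.5 U/ul, 1.23 and 1.25 times the shuffled level, and at 1.53 and 1.65 times in T1 libraries. ATTTA, an AU-rich element core, was near the shuffled level in both proteins. Among hexamers in at least 1% of clusters, TAGGAA was furthest above the shuffled level at 0.15 U/ul in FUBP3, at 2.06 times, and in KHSRP, at 2.08 times. In the T1 libraries ACTGTA led instead, at 2.33 and 3.23 times, and TAGGAA was not among the 10 highest.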

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

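The tests of overlapping T1 clusters, of distinct sequences in place of reads, of overlap by number of distinct sequences, of a matched minimum share of reads and of the microRNA share without the 5 most read short noncoding genes were chosen after the results were seen; the last 2 took the place of first tests on genes found in all 4 libraries, once those had been run and found void.

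FUBP3 and KHSRP T1 clusters carried gene names that did not match their positions. Names taken from another build's annotation stay open, since 73.8% of named T1 clusters lay inside the gene's extent in the AGO2 gel libraries and 60.2% inside its RefSeq span, short of either outcome that would decide. In the fluorescent libraries these shares were 13.7% and 99.4%, which the rule for deciding did not use. T1 names thus fell more often inside the gel libraries' extent, and less often inside RefSeq spans, than fluorescent names did. Only inside the gel libraries' extent lay 24.4% of T1 and 0.0557% of fluorescent clusters, and only inside the RefSeq span 10.7% and 85.8%. The extent spans only a gene's AGO2 clusters, so it can miss part of the gene. T1 clusters from other RNAs than the fluorescent ones is argued against only for those that overlapped a fluorescent one, at least 38.7% of T1 clusters with 10 or more reads. For the others it stays open, and no background overlap was set beside this share. No biological explanation was tested.

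The microRNA share of AGO2 reads was higher with the urea gel. A candidate explanation is that fewer mRNA clusters pass the caller's minimum in shallower libraries, since with a matched minimum the difference was 1.27 percentage points. Copies of a read sequence stay open. With distinct sequences the median difference was -0.85, but it covered genes with clusters in all 4 libraries. It cannot decide about mRNA clusters found only without the gel. Reads per distinct sequence were 4.98 and 3.28 without the gel and 2.55 and 1.85 with it. A few dominant microRNA genes were argued against by a difference of 15.0 percentage points without the reads of the 5 most read short noncoding genes. Selection of RNA by the gel itself stays open as untested, and no biological explanation was tested.

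Overlap between RNase I doses of FUBP3 was low. Clusters resting on 1 distinct sequence may account for part of it, since the share with a partner was 7.83 times higher at 3 or more sequences. Read number and cluster length were not held equal, so the ratio does not single out distinct sequences. In KHSRP at 0.15 U/ul the ratio was 15.4. There only 16.9% of clusters rested on 1 sequence, and 19.3% of those with 3 or more were shared. Cleavage at other positions cannot be told apart for FUBP3. Of its unshared clusters 18.1% had a neighbour within 100 nt, 2.23 times the moved clusters but far from the majority expected of a cause. A difference in binding between doses was not tested.

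Some shares of clusters moved in opposite directions between proteins from 0.15 to 1.5 U/ul RNase I, with 1 library each, and the differences between proteins were not tested. By reads FUBP3 moved the same way as AGO2, with 3' UTRs at 37.2% and 30.5% (AGO2 3.97% and 2.50%) and introns at 47.8% and 53.7% (AGO2 3.21% and 3.76%). KHSRP 3' UTRs held 8.65% and 8.77% of clusters and 11.8% and 10.3% of reads, so by reads the 3' UTR share was lower at 1.5 U/ul in all 3 proteins. The 3' UTR share moved by -8.90 points in AGO2 and 1.79 in FUBP3. The intron share moved by 4.65 points in AGO2, -1.77 in FUBP3 and -5.95 in KHSRP. The coding share moved by -3.34 points in AGO2, -0.238 in FUBP3 and 1.13 in KHSRP. Of CPSF1 clusters without an annotated gene, which entered the shares over all clusters but no comparison of genes, 16.8% held AATAAA or ATTAAA, 3.35 times the shuffled 5.01%.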

How the results depend on the processing

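The alternatives with a matched minimum share of reads, at least 3 distinct sequences, distinct sequences in place of reads, without short noncoding RNA genes and without names from rRNA loci were chosen after the results were seen; the causes of the shifts were not tested unless stated. Of 286 values tried for 62 results, 152 counted as unchanged, 15 lost their call, 10 reversed and the others moved. Unchanged meant, by kind of result, the same direction, a count of similar size, a value within its interval or spread, or the same side of the threshold. Reads in clusters and the read minimum limit how many clusters each library can share.

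For the AGO2 gel, with a matched minimum the log2 cluster number turned to -0.58, length to 6.50 nt, 3' UTR share to 0.0512 and seed share to 9.13 points, calls fell to 0 (edgeR, 40 at an unadjusted p under 0.05; DESeq2 not run), and the short noncoding list lost its call, its adjusted p rising to 0.147 and its median moving from -0.53 to -0.08. The 3' UTR difference was 2.70 with at least 10 reads, 0.35 for the top 1000, 9.46 by reads and 2.67 with at least 3 distinct sequences, and the seed difference 4.75 for the top 1000. Leaving out a library gave T-to-C differences from -0.316 to 0.0593 and from 0 to 14 calls, where a lone library is assumed to vary like the other group. Calls were 0 with genes in any library (edgeR, 1145 of 8350 at an unadjusted p under 0.05), 1 by 3' UTR reads, 5 by distinct sequences and 1 without short noncoding genes. The short noncoding list gave 0.375 with an estimated correlation. With the replicate letter as a block, the pairing correlation being -0.012 over 1121 genes, the differences were 2.91 in log2 cluster number, -1 nt in length, and -7.02, -0.128 and -9.81 points in 3' UTR, T-to-C and seed share, calls 3, EXOC8 3.30, MIR17HG -0.70 and MIR320A -1.22, and the adjusted list p-values 0.629 (microRNA targets), 0.246 (AU-rich), 0.629 (histones), 0.0521 (SR and hnRNP), 0.0732 (ribosomal) and 2.87e-11 (short noncoding).

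Overlap shares were, with at least 10 reads, the top 1000, overlap of 50% of each cluster and 3 distinct sequences: AGO2 53.5%, 58.5% and 36.8% (the last is not given here), FUBP3 0.5 U/ul 18.6%, 62.9%, 6.59% and 34.1%, FUBP3 1.5 U/ul 17.9%, 53.8%, 7.46% and 50.0%, KHSRP 0.5 U/ul 48.4%, 63.1%, 15.2% and 44.6%, KHSRP 1.5 U/ul 48.6%, 32.6%, 8.19% and 54.5%. T1 overlap was 55.0% and 11.5% in FUBP3 and 38.7% and 5.60% in KHSRP with 10 reads and 50% overlap, U2AF1 21.3% and 15.9%, and the shared AGO2 stretches 50.9%. The 3' UTR share at 0.5 U/ul, by reads and with 10 reads, was 10.9% and 14.2% in CPSF1, 37.0% and 38.1% in FUBP3 and 12.6% and 14.7% in KHSRP. AGO2 3' UTR shares with 10 reads and the top 1000 were 28.9% and 24.6% at 0.15 U/ul and 20.1% and 16.5% at 1.5 U/ul. The U2AF1 3' splice-site shares with 10 reads were 12.8% and 7.24%. U2AF1 intron shares of reads at 1.5 and 15 U/ml, 23.6% and 32.4%, were 16.9% and 12.2% without names from rRNA loci.

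CPSF1 hexamers stood in 22.7% with 10 reads and 33.1% with 3 distinct sequences, and 3' end shares were 2.46% at 50 nt, 3.48% at 200 nt, 4.70% with 10 reads and 10.1% with 3 distinct sequences. KHSRP-higher genes numbered 1056 with 10 reads, 52 with 200, 265 scaled, 22 in 3' UTRs and 58 with 3 distinct sequences, and FUBP3-higher 967, 2, 268, 3 and 24, or 177 without 1.5 U/ul. The 20 genes taken by the naming rule kept their direction under all 5 alternatives tried. For the alternatives that left out a dose this was fixed by the rule. Only median-of-ratios scaling and distinct sequences in place of reads could have turned it. Motif ratios with base counts, 10 reads and the top 1000 were 10.8, 4.19 and 4.24 in AGO2, 5.73, 4.99 and 6.37 in CPSF1, 1.44, 1.27 and 1.39 in FUBP3, 1.77, 1.30 and 1.32 in KHSRP, and 4.38, 2.04 and 2.53 in U2AF1. A splice-site distance of 20 or 100 nt and 50% overlap across AGO2 builds were not run.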

Other observations

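The counts of strong clusters missing at another dose and the lists with at least 10 reads were chosen after the results were seen.

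AGO2 clusters lay on the mRNA of AGO2 itself almost only in coding sequence, 22 of 22 clusters at 0.15 U/ul and 24 of 26 in library A without the gel. Reads from a tagged copy of AGO2 cannot be told from those of the native gene, so this says little about binding to the native mRNA. On their own mRNAs at 0.15 U/ul, 4 of 34 FUBP3 clusters and 2 of 8 KHSRP clusters were coding. FUBP3 and KHSRP, with at least 10 reads, differed on more lists. The 10 mRNAs with AU-rich elements had a median log2 ratio of 0.99 toward FUBP3, above 99.84% of random lists, with medians of 1.59, 1.21 and 0.06 from the lowest to the highest dose, and the 16 microRNA targets 0.68, above 99.61%, with medians of 0.75, 0.85 and 0.34 by dose. The 14 ribosomal protein mRNAs lay at -1.28 toward KHSRP, below all random lists, and the 28 SR and hnRNP mRNAs at -0.42, above 33.8%. The others lay within the random range, with 5 mitochondrially encoded RNAs at -0.23, 10 long noncoding RNAs (without LINC00657, missed by name) at -0.19, 9 3' end factors at -0.66, 7 genes of the FUBP family and tagged proteins at 0.26 and 6 short noncoding genes at -0.31. Means over doses hid changes of sign in the mitochondrially encoded RNAs (0.63, 1.56 and -2.18 by dose), the FUBP family with tagged proteins (1.05, 1.11 and -0.79) and the 3' end factors (-0.91, -1.07 and 0.03).

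Some strong clusters of FUBP3 and KHSRP were absent at a single dose. The HNRNPA2B1 3' UTR cluster (chromosome 7, hg38, 26191853 to 26192230) had 2844 reads from 669 distinct sequences at 0.15 U/ul, 241 reads at 1.5 U/ul and a T1 cluster, but no cluster at 0.5 U/ul. Of the 869 top 0.15 U/ul clusters also seen at 1.5 U/ul, 74 (8.52%) had no cluster at 0.5 U/ul, and 47 of these had one in T1. Over the 6 such comparisons the share ranged from 8.52% to 15.1% in FUBP3 and from 4.82% to 43.0% in KHSRP, where the highest values, 43.0% and 42.2%, were for clusters missing at 1.5 U/ul. Other FUBP3 examples were ITM2B (687 reads) and, missing at 1.5 U/ul, APP (587 reads).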
